A study of Mus musculus with 6 samples.

How the data were processed

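Livers of wild-type C57 mice that were 1 month old were measured on Affymetrix mouse expression arrays, 1 array per mouse. Per the labels, 3 livers came from mice given an adenoviral vector to overexpress TFEB and 3 from mice that were not injected. TFEB is a transcription factor known as a regulator of lysosomal and autophagy genes. The labels name no liver injected with an empty vector, so the injection, the vector and TFEB itself cannot be told apart in this design. Total RNA was turned into biotin-labelled cRNA, per the labels' protocols.

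The table holds log2 values per probe set, as the authors deposited them. The R package affy and RMA are named in the submitters' processing notes, with no version. RMA usually adjusts the background of perfect-match probes, equalises the distribution of intensities between arrays and combines the probes of a set by median polish. Whether filters were applied is not given in the sources used here. Because RMA equalises the arrays, a shift of all transcripts in 1 direction would not be seen, and low values are compressed towards a common floor. No detection calls came with the values, so no gene was called absent, and the number of arrays limits the precision.

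The table had 22690 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol to 20380 probe sets, several to 691 and none to 1555. Only probe sets with 1 symbol were named, which gave 12393 genes, 4956 of them with more than 1 probe set. Gene identifiers of 12369 genes were found in the RefSeq gene table of GRCm38.p6, and this changed 0 symbols. The value of a gene was that of its probe set with the highest mean over all 6 arrays. Among the 1600 called genes with more than 1 probe set, 37 had another probe set called in the opposite direction.

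Differences were tested with limma (version 3.58.1, R 4.3.3) using lmFit and eBayes, without a covariate and without a filter on low values. The test was two-sided and p-values were adjusted by the Benjamini-Hochberg method over 12393 genes. A gene was called at an adjusted p under 0.05, and the same calls were counted again at a fold change of at least 1.5. Differences are means of injected minus not-injected log2 values, each from 3 arrays, with the standard error of the moderated fit. The prior degrees of freedom of the variance were 3.47. The labels call the arrays biological replicates.

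The shift of each gene list against all other genes was tested with limma's camera at a preset correlation of 0.01, and p-values were adjusted over the 46 lists with at least 5 measured genes. Camera with a correlation estimated from the data was run beside it. The directional test of fry, which asks whether the genes of a list move on balance in 1 direction and does not set them against other genes, was also run. Members called were counted over all genes and again adjusted over the list alone. The lists covered lysosome, autophagy, nutrient sensing, lipid, bile acid and sugar metabolism, respiration, inflammation, stress, cell division, cell types, zonation, sex, clock, handling and gene families. They were fixed from textbook knowledge before the data were examined, as were the tests of genes and lists, the alternatives and the rule for named genes. Several tests of possible explanations were chosen later, as stated where they are given.

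The rule named the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap, and always Tfeb, Tfe3, Mitf, Ppargc1a and Ppara. It also named up to 3 called members with the smallest p for each main list and up to 2 for each other list. A list without a called member would have given its member with the smallest p. Tfe3 had no probe set with 1 symbol and was not analysed here.

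The scripts were tested on simulated data with the real genes, 3 arrays per group and 200 changed genes. Of genes changed by 0.5 on the log2 scale 62% were called, and of genes changed by 1 on that scale 89%. Unchanged genes made up 4.43% of the calls. All 3 planted lists and 0 of 42 lists without a planted gene were called. Genes were drawn independently of each other, so the simulation does not show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation within a list reached 0.47, in the periportal list.

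The alternatives were the replicate number as a block, variance moderation with an intensity trend, no moderation, genes at or above the median level, the mean of all probe sets, every probe set, a second quantile normalisation, centring on the median, array weights and leaving out each array in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and plots.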

Results

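Gene expression was measured in the livers of 3 mice given an adenoviral vector for TFEB and of 3 mice that were not injected, with 1 array per mouse. TFEB is a transcription factor of the MiT family that acts on lysosomal genes. The comparison asks which liver transcripts differ when TFEB is overexpressed. Correlations between arrays across probe sets were 0.997 to 0.998 among not-injected livers, 0.992 to 0.997 among injected livers and 0.974 to 0.988 between groups. Probe sets are not independent replicates. The control probe sets also differed. The 18 probe sets of hybridisation spike-ins had a median difference of -0.32, injected minus not-injected, and in all 18 every injected array lay below every not-injected array. The 24 probe sets of poly-A spike-ins had a median of -0.44, and in 23 the groups were apart in this way. The labels give neither the amounts added nor the order of labelling and hybridisation. A batch in labelling or hybridisation that coincides with injection is therefore not excluded for any difference between the groups. The spike-ins spanned -0.57 to -0.06 and do not bound the size or direction of such an effect on other probe sets. The difference between the 3' and 5' probe sets of Gapdh was 0.34 ± 0.05 (SD, n = 3) in not-injected and 0.21 ± 0.05 (SD, n = 3) in injected livers, and that of Actb was 1.36 ± 0.06 and 1.38 ± 0.11.

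The only probe set of Tfeb read 7.52 ± 0.06 (SD, n = 3) without injection and 7.58 ± 0.18 (SD, n = 3) with it. The difference of 0.05 was within the spread of the arrays (two-sided exact permutation p = 0.9 over 20 assignments, smallest possible 0.1). It read -0.05 without injected replicate 2. The labels do not give the sequence of the transgene, so it is open whether these probes can detect it, and the value does not check the labels. Of the related Mitf, the difference was -0.22 ± 0.07 (limma adjusted p = 0.06), and it passed the threshold after a second quantile normalisation (adjusted p = 0.0484), with array weights (adjusted p = 0.018) and without injected replicate 2 (-0.27, adjusted p = 0.0232). The other probe set of Mitf read -0.077 (exact permutation p = 0.4). Its means of 4.16 without injection and 4.08 with it lay below the lower quartile of every array (5.46 or more), so it is little evidence either way. Tfe3 was not analysed here. Ppargc1a, which encodes the coactivator PGC-1 alpha, rose 4.71-fold (2.24 ± 0.15 on the log2 scale, adjusted p = 0.000122). Ppara, which encodes a nuclear receptor of fatty acid metabolism, read 0.03 ± 0.07 (adjusted p = 0.761).

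Injected livers differed widely from livers that were not injected. Gpnmb, which encodes a lysosomal and melanosomal glycoprotein, rose 136-fold (7.08 ± 0.58 on the log2 scale, SE), the largest rise among called genes with separate groups. Bex2 rose 55.6-fold, the secreted glutathione peroxidase Gpx3 48.7-fold, the prostaglandin receptor Ptger3 42.7-fold, Ly6d 36.3-fold and the metallothionein Mt1 22.4-fold. The largest falls were in Hsd3b5, a steroid dehydrogenase of male mouse liver, which fell 23.3-fold, and in the adipokine gene Serpina12, which fell 14.8-fold. The haemoglobin scavenger receptor Cd163 was 12.3-fold lower, the fatty acid elongase Elovl3 10.5-fold lower and the anion transporter Slc22a7 6.59-fold lower. The glycogen-targeting subunit Ppp1r3c was 6.45-fold lower, the organic anion transporter Slco1a1 6.12-fold lower and the oxysterol hydroxylase Cyp7b1 5.94-fold lower. All of these passed limma with an adjusted p of 0.0096 or less. Without variance moderation Hsd3b5 (adjusted p = 0.059), Slco1a1 (0.0831) and Cyp7b1 (0.0577) did not pass. Ptger3 without injection (mean 3.98) and Cd163 with it (mean 4.98) read below the lower quartile of every array (5.46 or more). Presence above background was not measured, so the folds of both are not exact. Without injection Gpnmb read 5.60 on average, at about that quartile, and its fold is not exact either.

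In total 3486 of 12393 genes (28.1%) were called by limma, 1765 higher and 1721 lower in injected livers. At 1.5-fold or more there were 1190, of which 781 were higher and 409 lower, and at 4-fold or more 90 were higher and 14 lower. The groups did not overlap in 5731 genes (46.2%), where chance gives 10%, and in 3476 of the called genes. The median difference over all genes was -0.049. Of the 1721 lower genes, 702 lay below the poly-A spike-in median of -0.44, a count made after the spike-ins had been seen. A batch is not excluded for these genes either. The count of called genes was 1973 without not-injected replicate 2, 2032 without not-injected replicate 3, 2103 without injected replicate 1 and 4378 without injected replicate 2. The same livers decided part of the sizes. Bex1 rose 58.6-fold and the calcium-binding S100a6 rose 21.9-fold over all arrays, but injected replicate 2 read 5.12 for Bex1 against 12.2 and 12.3 in the other injected livers, and 5.95 for S100a6 against 11.4 in both. Without injection both genes read below the lower quartile of every array (means of 4.0 and 5.12), which leaves their folds inexact. Without injected replicate 1, 3 or any of the not-injected arrays both genes lost their call, with adjusted p-values of 0.0988 to 0.127 for Bex1 and 0.0896 to 0.129 for S100a6. Without injected replicate 2 the rises were larger for Gpnmb (7.85), Bex1 (8.25), Ptger3 (6.28), Ly6d (5.77) and S100a6 (6.26), and the falls were larger for Hsd3b5 (-5.51) and Slco1a1 (-3.22). Without injected replicate 1 the values were -3.83 for Hsd3b5, -2.76 for Elovl3 and -2.01 for Slco1a1. With the mean of all probe sets Ptger3 read 2.71, Mt1 2.18 and Serpina12 -2.49.

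**Figure D1:**
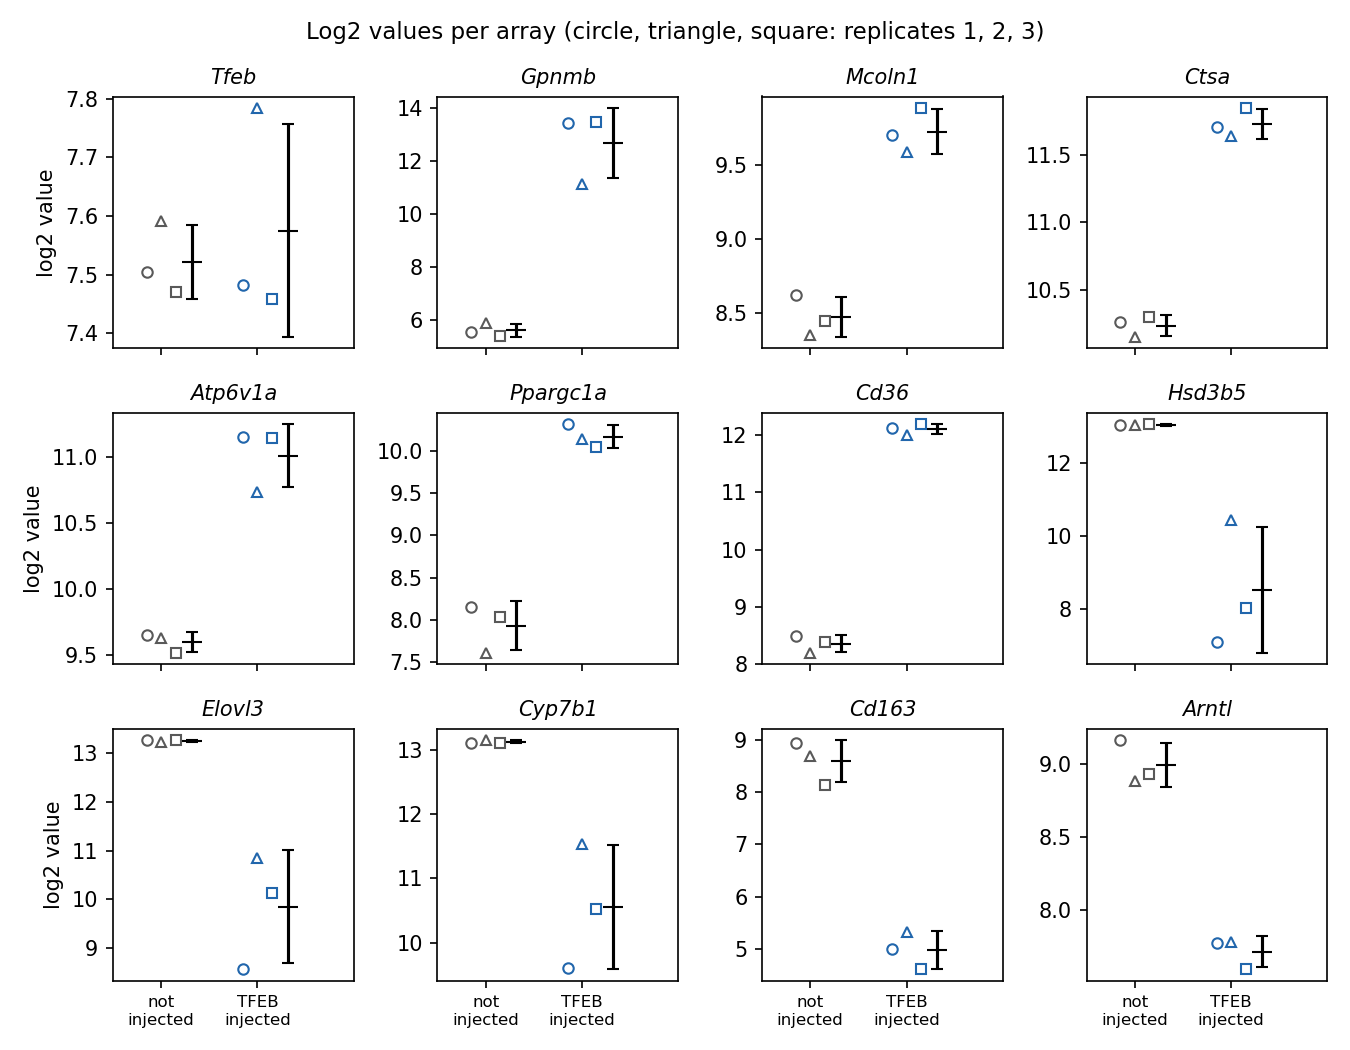
Log2 values of 12 genes on each of the 6 arrays, with not-injected livers in grey and TFEB-injected livers in blue and with mean ± SD in black; each panel has its own vertical axis, which does not start at 0. Injected replicate 2 (triangle) reads 11.1 for Gpnmb, below the 13.4 and 13.5 of the other injected livers, while the groups overlap only for Tfeb.

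Most measured lysosomal enzyme genes were higher in injected livers. Of 46 lysosomal hydrolases and activators, 29 rose, 2 fell and 15 did not pass (32 higher and 3 lower adjusted over the list alone). The sialidase Neu1 rose 3.01-fold (1.59 ± 0.08), its protective partner cathepsin A, encoded by Ctsa, 2.82-fold (SE 0.08 on the log2 scale) and cathepsin Z, encoded by Ctsz, 2.63-fold (1.40 ± 0.07). With the mean of its probe sets Neu1 read 0.91. The median of the list was 0.46 (camera adjusted p = 2.5e-10; adjusted p = 0.44 with an estimated correlation). All of the 20 vacuolar ATPase subunits that passed were higher, 13 in number (15 higher and 0 lower adjusted over the list alone), and 7 did not pass. This proton pump acidifies lysosomes. Atp6v1a rose 2.65-fold (1.41 ± 0.12), Atp6v1d 1.78-fold (0.83 ± 0.07) and Atp6v1e1 1.77-fold (0.83 ± 0.08), and the list median was 0.50 (camera adjusted p = 1.3e-07; adjusted p = 0.44 with an estimated correlation). Among 34 lysosomal membrane proteins 17 rose, 5 fell and 12 did not pass, with the same counts adjusted over the list alone. The calcium channel Mcoln1 rose 2.38-fold (1.25 ± 0.10) and the phosphatase Pip4p2 1.55-fold (0.63 ± 0.06). The list median was 0.22 (camera adjusted p = 0.00028; adjusted p = 0.44 with an estimated correlation), and it was 0.44 among genes at or above the median level.

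Autophagy genes moved both ways. Of 46, 14 rose, 9 fell and 23 did not pass (17 higher and 10 lower adjusted over the list alone). Gabarapl1 and Map1lc3b, which encode proteins conjugated to autophagosome membranes, rose by 1.14 ± 0.08 and 0.70 ± 0.08, and Atg101, a subunit of the initiating kinase complex, fell by 0.89 ± 0.11. The list median was 0.09 (camera adjusted p = 0.046; adjusted p = 0.44 with an estimated correlation). The call was lost without any of the not-injected arrays or injected replicate 1 (adjusted p 0.0512 to 0.0953), after a second quantile normalisation (adjusted p = 0.182) and among genes at or above the median level (adjusted p = 0.193). In nutrient sensing at the lysosome 8 of 22 genes rose and 0 fell, and 14 did not pass (9 higher and 0 lower adjusted over the list alone). Flcn, which encodes folliculin, rose 2.15-fold (1.10 ± 0.07), the Rag GTPase Rragc 1.96-fold (0.97 ± 0.08) and the mTORC1 target Eif4ebp1 1.70-fold (0.76 ± 0.09). Its median was 0.10 (camera adjusted p = 0.0058; adjusted p = 0.44 with an estimated correlation), with the call lost among genes at or above the median level (adjusted p = 0.0573) and a median of 0.06 without not-injected replicate 1.

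All called genes of the respiratory chain were higher. Of 51 respiratory chain genes 28 rose, 0 fell and 23 did not pass (32 higher and 0 lower adjusted over the list alone). Ndufs1 of complex I rose by 0.52 ± 0.07, Uqcrfs1 of complex III by 0.49 ± 0.07 and cytochrome c, encoded by Cycs, by 0.42 ± 0.06, and the list median was 0.23 (camera adjusted p = 2.8e-10; adjusted p = 0.44 with an estimated correlation). Of 48 genes of fatty acid oxidation and PPAR-alpha targets 16 rose, 1 fell and 31 did not pass, with the same counts adjusted over the list alone. The fatty acid transporter Cd36 rose 13.4-fold (3.74 ± 0.09), the pantetheinase Vnn1 6.64-fold (2.73 ± 0.09), Cyp4a14 by 3.75 ± 0.54 and the pyruvate dehydrogenase kinase Pdk4 by 4.03 ± 0.32. The list median was 0.17 (camera adjusted p = 4.2e-05; adjusted p = 0.44 with an estimated correlation), and it was 0.10 without injected replicate 3 (camera adjusted p = 0.00047). Fatty acid and triglyceride synthesis was divided, with 8 of 36 genes higher, 13 lower and 15 that did not pass (8 higher and 14 lower adjusted over the list alone). The lipid droplet gene Plin4 rose 5.86-fold (2.55 ± 0.10), the nuclear receptor Pparg 2.67-fold (1.42 ± 0.12) and the mitochondrial acetyl-CoA carboxylase Acacb 2.39-fold (1.26 ± 0.10). The sterol and lipid regulator Srebf1 fell by 1.32 ± 0.12, fatty acid synthase, encoded by Fasn, by 1.21 ± 0.16, and Thrsp by 1.67 ± 0.30. Many of these lipid genes respond to fasting and feeding, and the labels do not give the feeding state at harvest. The median of -0.03 did not pass (camera adjusted p = 0.89).

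Several hepatocyte functions had lower transcripts, in the same direction as the spike-in medians of -0.32 and -0.44. Of 29 genes of bile acid synthesis and transport 14 fell, 0 rose and 15 did not pass (18 lower and 1 higher adjusted over the list alone). The receptor Fgfr4, which mediates feedback on bile acid synthesis, fell by 1.11 ± 0.10, the oxidase Acox2 by 0.72 ± 0.07 and the hydroxylase Cyp27a1 by 0.66 ± 0.08. Fgfr4 read -0.44 with the mean of its probe sets. This list had a median of -0.55 (camera adjusted p = 0.00014; adjusted p = 0.44 with an estimated correlation). In cholesterol synthesis and uptake 9 of 23 genes fell, 2 rose and 12 did not pass (11 lower and 2 higher adjusted over the list alone). Mvd of the mevalonate pathway fell by 1.33 ± 0.18, the sterol carrier Stard4 by 1.09 ± 0.12 and squalene synthase, encoded by Fdft1, by 0.85 ± 0.09. Over the list the median was -0.36 (camera adjusted p = 0.0021; adjusted p = 0.52 with an estimated correlation). Of 33 genes of xenobiotic metabolism 15 fell, 3 rose and 15 did not pass (18 lower and 4 higher adjusted over the list alone). The carboxylesterases Ces2a and Ces1d fell by 1.91 ± 0.18 and 1.06 ± 0.13 and Cyp2d10 by 0.60 ± 0.07, with a list median of -0.42 (camera adjusted p = 0.0099; adjusted p = 0.44 with an estimated correlation). In gluconeogenesis and glycolysis 8 of 22 genes fell, 3 rose and 11 did not pass (8 lower and 5 higher adjusted over the list alone). Glucose-6-phosphatase, encoded by G6pc, fell 3.34-fold (-1.74 ± 0.13) and tyrosine aminotransferase, encoded by Tat, 2.74-fold (-1.45 ± 0.10), while the list median of -0.13 did not pass (camera adjusted p = 0.11). That median was -0.08 without injected replicate 3, and fry called the list (adjusted p = 0.0054).

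**Figure D2:**
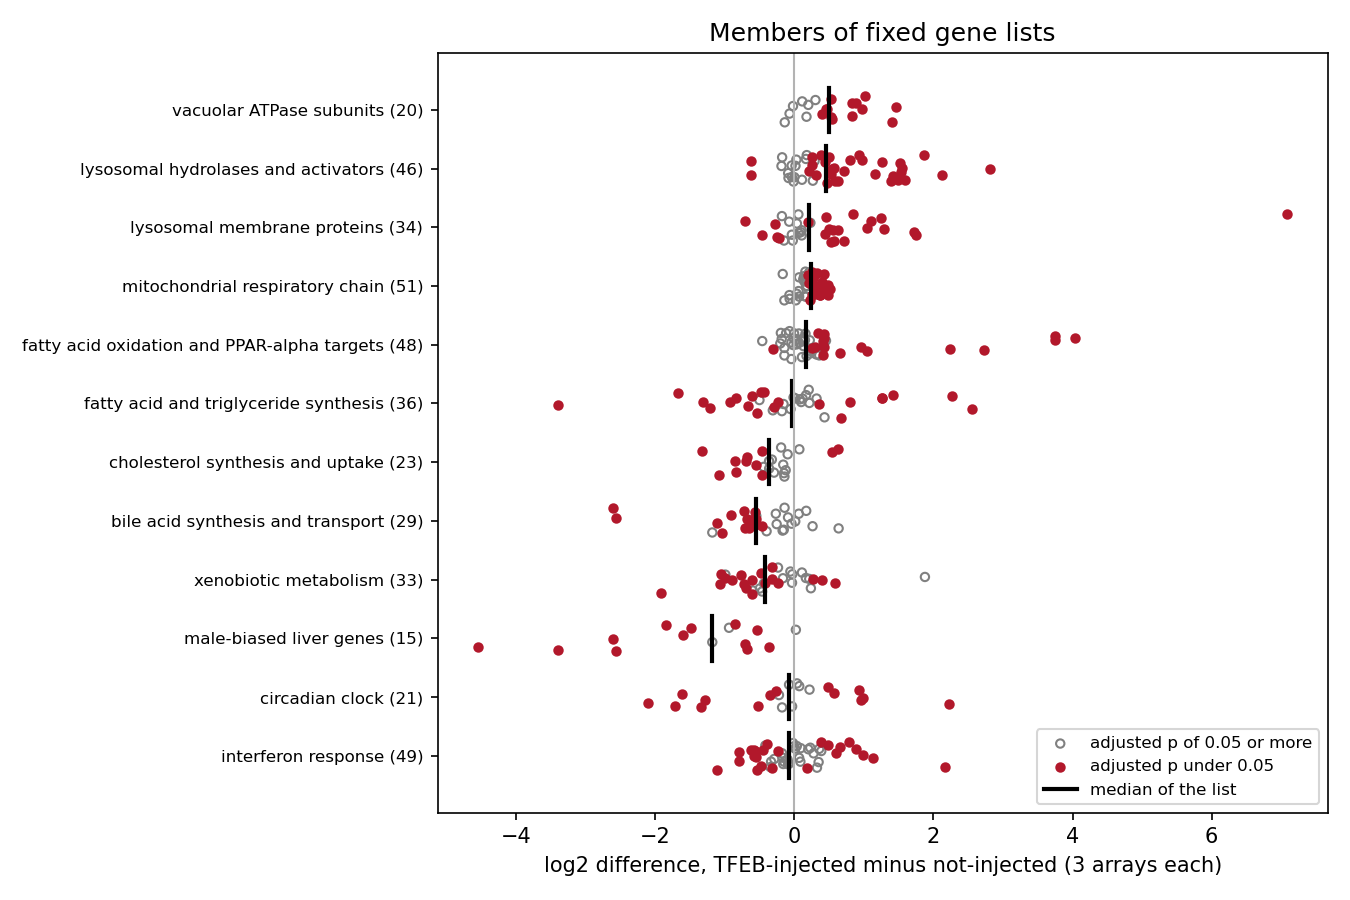
Log2 difference, TFEB-injected minus not-injected (3 arrays each), of every measured member of 12 gene lists, with the number measured in brackets; filled points had a limma adjusted p under 0.05, open points did not and black bars are list medians. The medians run from 0.50 in vacuolar ATPase subunits to -1.18 in male-biased genes, and clock, interferon and lipid synthesis genes lie on both sides of 0.

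Inflammatory and stress lists held opposed members. Of 49 interferon response genes 10 rose, 14 fell and 25 did not pass (13 higher and 17 lower adjusted over the list alone). Usp18, an interferon-induced deconjugating protease, rose 4.49-fold (2.17 ± 0.14), and the MHC class II genes H2-Ab1 and H2-Aa rose by 1.13 ± 0.10 and 0.99 ± 0.10. The antiviral gene Ifit1 fell by 1.11 ± 0.12 and the regulator Irf7 by 0.55 ± 0.08. The median was -0.07, the mean 0.01 and the test pointed up (camera adjusted p = 0.89). In the acute phase response 9 of 30 genes rose, 7 fell and 14 did not pass (10 higher and 8 lower adjusted over the list alone). Mt2 rose 12.3-fold (3.62 ± 0.38) and Lcn2 2.36-fold (1.24 ± 0.13), and the median of -0.08 differed in sign from the mean of 0.36 and the test (camera adjusted p = 0.42). In the oxidative stress response 8 of 23 genes rose, 6 fell and 9 did not pass (8 higher and 7 lower adjusted over the list alone). Heme oxygenase, encoded by Hmox1, rose by 1.34 ± 0.14 and Akr1b8 by 0.99 ± 0.14, while the aldehyde oxidase Aox1 fell by 1.21 ± 0.10. The median of -0.02 differed in sign from the mean of 0.10 and the test (camera adjusted p = 0.76). Of 35 genes of the unfolded protein and amino acid stress responses 16 fell, 4 rose and 15 did not pass (17 lower and 6 higher adjusted over the list alone). The endoplasmic reticulum chaperone Hyou1 fell by 0.76 ± 0.06 and Pdia4 by 0.68 ± 0.07, whereas the stress-induced Nupr1 rose 7.68-fold (2.94 ± 0.24). The list median was -0.22 and the mean -0.01 (camera adjusted p = 0.046; adjusted p = 0.52 with an estimated correlation). The call was lost without injected replicate 1 (0.0636), injected replicate 2 (0.115) or not-injected replicate 3 (0.13), with the mean of all probe sets (0.0835), after a second quantile normalisation (0.06) and after centring (0.0647), all adjusted p-values of camera. Of 46 cell cycle genes 9 rose, 3 fell and 34 did not pass (12 higher and 4 lower adjusted over the list alone). The cyclin Ccnb2 rose by 0.88 ± 0.16 and the spindle protein Nusap1 by 0.69 ± 0.11, while thymidine kinase, encoded by Tk1, fell by 0.52 ± 0.09. The median was 0.17 (camera adjusted p = 0.019; adjusted p = 0.52 with an estimated correlation), and it was 0.09 without not-injected replicate 3 (camera adjusted p = 0.0492). The call was lost without injected replicate 1 (adjusted p = 0.0607) and by fry (adjusted p = 0.152).

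Of 23 Kupffer cell and macrophage markers 6 rose, 2 fell and 15 did not pass (8 higher and 2 lower adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0061; adjusted p = 0.52 with an estimated correlation) that ran from 0.11 without not-injected replicate 3 to 0.31 without not-injected replicate 1. The endotoxin co-receptor Cd14 rose 3.03-fold (1.60 ± 0.19), Cd163 was lower by an inexact amount, and fry did not call the list (adjusted p = 0.125). Of 21 markers of sinusoidal endothelial cells 6 rose, 0 fell and 15 did not pass, with the same counts adjusted over the list alone. The hyaluronan receptor Lyve1 rose 4.28-fold (2.10 ± 0.15) and Flt4 1.58-fold (0.66 ± 0.07). The median was 0.22 (camera adjusted p = 0.0023; adjusted p = 0.52 with an estimated correlation), and fry did not call it (adjusted p = 0.056). Of 11 B and plasma cell markers 3 rose and 1 fell over all genes and over the list alone. The adaptor Blnk rose 8.25-fold (3.04 ± 0.15) and Jchain by 0.59 ± 0.12, while Ighm read -1.90 (limma adjusted p = 0.0099). The median of these markers was 0.01 (camera adjusted p = 0.17, fry adjusted p = 0.013). Only Ccl5 passed among 22 T and NK cell markers (0.89 ± 0.24), 0 did adjusted over the list alone, and Ccl5 lost its call without any single array other than injected replicate 3 (adjusted p 0.0519 to 0.0956). That list had a median of -0.07 and a mean of 0.00 (camera adjusted p = 0.76). Of 13 neutrophil markers 2 rose, Lcn2 and S100a8 (0.74 ± 0.23), and 1 did adjusted over the list alone. S100a8 lost its call without any of the not-injected arrays (adjusted p 0.0911 to 0.143) and read 0.45 without injected replicate 1, and the list median of -0.02 differed in sign from its mean of 0.16 (camera adjusted p = 0.50).

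Of 22 stellate cell and fibroblast markers 2 rose and 2 fell (1 and 1 adjusted over the list alone). Vim rose by 0.83 ± 0.18 and Ecm1 fell by 0.50 ± 0.11, but Vim did not pass without not-injected replicate 2 (adjusted p = 0.0579) or 3 (adjusted p = 0.0532). The median of 0.15 did not pass (camera adjusted p = 0.094), and it was 0.06 without injected replicate 1 and 0.20 without injected replicate 2, where the list was called (adjusted p = 0.00921), as it was with array weights (median 0.17, adjusted p = 0.0334). With the mean of all probe sets the median was 0.082, and among genes at or above the median level it was 0.44, both uncalled. Of 15 cholangiocyte and progenitor markers 3 rose and 0 fell by either adjustment. Aqp1 rose by 0.58 ± 0.10 and Cd24a by 0.88 ± 0.19, the latter lost without not-injected replicate 2 (adjusted p = 0.0585). The median of 0.12 did not pass (camera adjusted p = 0.19) except without injected replicate 2, where it was 0.36 (adjusted p = 0.0443), and it was 0.03 without injected replicate 3. Of 7 erythroid and blood markers 1 fell by either adjustment, Alas2 (-1.60 ± 0.16), with a median of -0.02 (camera adjusted p = 0.71), and of 11 pancreatic acinar markers 2 fell by either adjustment, Cela1 (-1.19 ± 0.16) and Cela2a (-0.44 ± 0.09), with a median of -0.12 (camera adjusted p = 0.17) that was -0.06 without not-injected replicate 2 or injected replicate 1. Of 26 hepatocyte secretory and identity genes 7 fell, 3 rose and 16 did not pass (9 lower and 3 higher adjusted over the list alone). Prothrombin, encoded by F2, fell by 0.35 ± 0.06. The median of -0.14 did not pass (camera adjusted p = 0.094), although it passed with an intensity trend in the variance (adjusted p = 0.0498) and by fry (adjusted p = 0.0098).

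Most genes with a male bias in mouse liver were lower. Of 15 male-biased genes 12 fell, 0 rose and 3 did not pass (13 lower and 0 higher adjusted over the list alone), with a median of -1.18 (camera adjusted p = 1.6e-05; adjusted p = 0.44 with an estimated correlation). Besides Hsd3b5, Elovl3, Slco1a1 and Cyp7b1 they included Ugt2b38, which fell 3.57-fold (-1.84 ± 0.25). Of 21 female-biased genes 5 rose, 1 fell and 15 did not pass by either adjustment. Lipoprotein lipase, encoded by Lpl, rose 2.72-fold (1.45 ± 0.08) and Fmo2 3.87-fold (1.95 ± 0.26), although Fmo2 read 0.87 with the mean of its probe sets. The median was 0.11 (camera adjusted p = 0.046; adjusted p = 0.44 with an estimated correlation), and the call was lost without any single array other than injected replicate 2 (adjusted p 0.0512 to 0.0789), with medians from 0.09 without injected replicate 3 to 0.25 without injected replicate 2. Of 4 sex chromosome genes Uty rose (0.31 ± 0.07), a call lost without not-injected replicate 2, not-injected replicate 3 or injected replicate 1 (adjusted p 0.0563 to 0.0674). Both zonation lists had medians below 0. Of 26 pericentral genes 12 fell, 1 rose and 13 did not pass (14 lower and 2 higher adjusted over the list alone), including Cyp27a1 and the amino acid transporter Slc1a4 (-0.94 ± 0.11), with a median of -0.44 (camera adjusted p = 0.0099; adjusted p = 0.52 with an estimated correlation). Of 14 periportal genes 6 fell, 2 rose and 6 did not pass (7 lower and 2 higher adjusted over the list alone), G6pc among the lower and the dehydrogenase Aldh1b1 among the higher (1.45 ± 0.18). The median of -0.25 did not pass (camera adjusted p = 0.094). It was -0.15 without injected replicate 3, and the list was called without injected replicate 1 (adjusted p = 0.0474).

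Genes of the circadian clock list, which holds clock outputs such as Dbp beside core genes, split into higher and lower members. Of 21, 8 fell, 6 rose and 7 did not pass by either adjustment. The activator Arntl read -1.28 ± 0.10, Npas2 -1.72 ± 0.19, the repressor Cry1 -2.11 ± 0.22 and Nfil3 -1.61 ± 0.13, whereas Dbp rose by 2.22 ± 0.35 and Nr1d2 by 0.94 ± 0.10. Nr1d1 read -0.03 ± 0.10 (adjusted p = 0.845). Their median was -0.08 (camera adjusted p = 0.79). Neither the hour at which livers were taken nor the feeding state is given in the labels. Of 28 immediate early and handling stress genes 10 rose, 0 fell and 18 did not pass (12 higher and 0 lower adjusted over the list alone). The transcription factors Klf6 and Klf10 rose 5.64-fold (SE 0.22 on the log2 scale) and 2.59-fold (1.37 ± 0.10). The median was 0.29 (camera adjusted p = 0.0041; adjusted p = 0.44 with an estimated correlation), and it was 0.08 among genes at or above the median level, where the call was lost (adjusted p = 0.193). Npas2, Cry1, Dbp, Nr1d2, Nr1d1, Srebf1, Fasn, Thrsp, Ifit1, Irf7, Ighm, Cyp4a14 and Pdk4 were chosen after their values were seen.

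Over all lists camera called 21 of 46, 13 up and 8 down, and fry called 23. Some lists share members, such as Cyp7b1 and Slco1a1 in the bile acid and male-biased lists and Cyp2c29 in the xenobiotic and pericentral lists. Calls of such lists are not separate findings. Camera with an estimated correlation called 0, with 3 lists at an unadjusted p under 0.05. That form rests on the few degrees of freedom of the 6 arrays. The lost calls therefore do not show that correlation between genes accounts for them. The autophagy and UDP-glucuronosyltransferase lists lost their calls at estimated correlations of -0.012 and -0.019, below the preset 0.01. When the arrays were regrouped into the other splits of 3 against 3, limma called 0 genes in each, with up to 676 genes at an unadjusted p under 0.05, but camera called up to 19 lists. Each of these splits mixes injected and not-injected arrays on both sides. The difference between the livers then adds to the spread within groups, so the 0 calls do not measure what chance would give.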

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

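The count of unnamed probe sets was singled out after the data had been seen. The comparison of genes left out 2246 probe sets to which the annotation gave no gene symbol or several. By limma, adjusted over all probe sets other than controls, 412 of these were called, 182 higher and 230 lower in injected livers. This is a smaller share than the 28.1% of named genes. In all 182 every injected array read higher than every not-injected array. Such separation comes almost with the call, as it held in 3476 of the 3486 called genes, and it adds no further signal. The transcripts of these probe sets are not identified here.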

How the results depend on the processing

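All alternatives here were planned before the data were examined. The calls of 100 of the 114 called named genes held without each array in turn, 14 lost the call at least once and 0 changed sign. Most named genes were picked for small p-values or large changes in these data, which favours them in this count. Of all 3486 called genes, 1954 kept the call without not-injected replicate 2 and 3313 without injected replicate 2, the lowest and highest such counts. Counts of called genes stayed within 1.5 times of the report's under the trend (3502), the mean of probe sets (3423), a second quantile normalisation (3553), centring (3498) and array weights (4707). The level filter gave 2831 calls among 6197 genes tested, of which the main test had called 2493. The median of all genes read -0.046 after quantile normalisation and -0.067 after centring. Both scalings act on values that RMA usually equalises already, so this median had little room to move. Without moderation 1881 genes were called, 919 higher and 962 lower, and 744 at 1.5-fold or more with 459 higher; fewer degrees of freedom per gene enter that test. Of the named genes 19 lost their call there. Besides genes that also lost it without an array, these were Hsd3b5, Slco1a1, Cyp7b1, Ccnb2, Jchain, Ecm1, Cela2a, Psmd8 and Gsta2 (adjusted p 0.0558 to 0.0831). With the intensity trend Bex1 (adjusted p = 0.134), S100a6 (0.136), S100a8 (0.0618) and Mup3 (0.0538) lost their calls and the hepatocyte list gained one (0.0498). With the mean of probe sets the differences of Atp6v1e1 (0.545), Fdft1 (-0.51), Pdia4 (-0.34), Nusap1 (0.33), Flt4 (0.435) and Slc1a4 (-0.45) were smaller by more than 1.5 times, with the calls kept. Cela2a, Jchain, Nusap1 and S100a8 also read below the lower quartile of every array in 1 of the groups, so their sizes are inexact. With every probe set tested, 5662 were called, 2791 higher and 2871 lower, and 1955 at 1.5-fold or more, 1273 higher and 682 lower, a larger number of features by construction. Leaving out each array gave 1973 to 4378 called genes, 1036 to 2149 higher and 936 to 2229 lower.

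Replicate numbers are shared by both groups. The deviations of same-numbered arrays correlated at 0.14, 0.08 and 0.02, and those of other pairs at -0.19 to 0.06. The same-numbered array was the closest for injected replicates 1 and 2. Injected replicate 3 was closer to not-injected replicate 2 (0.06) than to not-injected replicate 3. With so few arrays these values do not settle whether the numbers pair the livers. With the replicate number as a block 3348 genes were called, 3074 of them among the 3486. A balanced block leaves the differences as they are. The unfolded protein list (median -0.22) lost its call (camera adjusted p = 0.0593), as did Rps6 among the named genes (limma adjusted p = 0.0542), and cytochrome P450 family 2 also lost its call (adjusted p = 0.065) while stellate cell markers gained one (adjusted p = 0.0442).

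With an estimated correlation all 21 list calls were lost at unchanged medians, among them 0.46 for hydrolases, 0.22 for membrane proteins, 0.50 for vacuolar ATPase, 0.093 for autophagy, 0.10 for nutrient sensing, 0.17 for fatty acid oxidation, -0.36 for cholesterol, -0.55 for bile acids, 0.23 for the respiratory chain, -0.22 for unfolded protein, -0.42 for xenobiotic and 0.17 for cell cycle genes (adjusted p of 0.439 or more). By fry the cell cycle list (0.17) lost its call, gluconeogenesis (-0.13) gained one, and oxidative stress (-0.021) and cytochrome P450 family 4 (0.072) changed the direction of the test, uncalled. Among genes at or above the median level autophagy (0.093), cell cycle (0.41) and nutrient sensing (0.10) lost their calls, with fewer genes tested. Acute phase (-0.093), interferon (-0.11), oxidative stress (-0.15) and cytochrome P450 family 4 (-0.57) changed the direction of the test there, uncalled. The unfolded protein list lost its call after centring (-0.24), with the mean of probe sets (-0.21) and after quantile normalisation (-0.17), as did autophagy after the latter (0.032). Quantile normalisation turned the direction of the test, uncalled, for T and NK cell markers (-0.024), interferon (-0.074), ribosomal proteins (-0.030), sulfotransferases (-0.00087), and the sign of Ppara (-0.0047). Array weights did so for cytochrome P450 family 4 (0.028), lipid synthesis (0.0055) and ribosomal proteins (-0.015), and the mean of probe sets for the clock (-0.031). The cause was not tested for these changes.

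Without each array in turn the medians ran from 0.0505 to 0.12 for autophagy, from 0.0914 to 0.21 for cell cycle, from -0.25 to -0.17 for unfolded protein, from -0.0682 to 0.0095 for lipid synthesis, from -0.0693 to -0.0015 for interferon, from 0.011 to 0.11 for cytochrome P450 family 4, from -0.087 to -0.021 for T and NK cells, from -0.13 to 0.031 for the clock, from -0.049 to -0.0094 for ribosomal proteins and from -0.10 to -0.051 for serpins, with a change of the call or of the direction of the test in each. Tfeb ran from -0.05 to 0.11 and Ppara from -0.013 to 0.078, both uncalled.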

Other observations

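The tests by regrouping the arrays, on the growth hormone response and on level-matched random lists were set before their results were seen. Those on macrophage markers, an empty vector, female livers, the share of hepatocytes and both on replicate 2 were chosen after. The bootstrap intervals given below resampled genes, which are not independent, and do not measure the spread between livers. Of 8 UDP-glucuronosyltransferases 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them Ugt2b38 and Ugt2b5 (-0.32 ± 0.06), with a median of -0.53 (camera adjusted p = 0.0035; adjusted p = 0.44 with an estimated correlation). In cytochrome P450 family 2, 14 of 31 genes fell and 3 rose (18 and 4 adjusted over the list alone). Cyp2d13 fell by 1.20 ± 0.07 and Cyp2j9 rose by 0.97 ± 0.07, and the median was -0.42 (camera adjusted p = 0.046; adjusted p = 0.44 with an estimated correlation). That call was lost without not-injected replicate 2 or 3 or injected replicate 3 (adjusted p 0.0512 to 0.0596), after centring (0.0655), after a second quantile normalisation (0.0907) and with the mean of probe sets (0.0633). Of 5 family 3 genes 2 rose and 1 fell by either adjustment, with Cyp3a44 at 0.32 ± 0.06 and Cyp3a11 at 0.27 ± 0.06 (median 0.24, camera adjusted p = 0.17; fry adjusted p = 0.0055), and Cyp3a11 lost its call without not-injected replicate 2, injected replicate 1 or injected replicate 3 (adjusted p 0.053 to 0.0662). Of 10 family 4 genes 3 rose and 4 fell (4 and 4 adjusted over the list alone), with Cyp4f14 at -1.07 ± 0.08 and Cyp4f13 at -0.79 ± 0.09 (median 0.07, camera adjusted p = 0.93). Of 11 sulfotransferases 2 rose and 1 fell by either adjustment. Sult1a1 fell by 0.72 ± 0.09 and Sult1c2 rose by 1.33 ± 0.31, a call lost without not-injected replicate 2 or 3 (adjusted p = 0.0684 and 0.0664), and the median was -0.04 (camera adjusted p = 0.89). Of 18 glutathione S-transferases 6 fell and 2 rose (6 and 4 adjusted over the list alone), with Gstm6 at -0.72 ± 0.11 and Gsta2 at 1.03 ± 0.18 (median -0.15, camera adjusted p = 0.42). Of 2 major urinary protein genes measured Mup3 fell by 0.68 ± 0.18, and lost its call without any array but injected replicate 2 (adjusted p 0.0609 to 0.0894); with the mean of its probe sets it read -2.13.

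Of 50 Rab GTPases 14 rose and 4 fell (14 and 5 adjusted over the list alone); Rab30 rose 7.61-fold (2.93 ± 0.40) and Rab1a 1.43-fold (0.51 ± 0.06), with a median of 0.01 (camera adjusted p = 0.13; fry adjusted p = 0.013). Of 265 solute carriers 48 fell and 33 rose (49 and 34 adjusted over the list alone), with Slc16a7 up 4.68-fold (2.23 ± 0.08) and Slc22a7 down (median -0.08, camera adjusted p = 0.42). Of 28 serpins 7 fell and 4 rose (7 and 5 adjusted over the list alone). Serpinb8 rose by 2.18 ± 0.16 and Serpinb9 by 1.23 ± 0.11, and the median of -0.07 differed in sign from the mean of 0.19 (camera adjusted p = 0.67). Of 12 peroxins 5 fell and 0 rose by either adjustment, with Pex16 at -0.41 ± 0.07 and Pex2 at -0.38 ± 0.08 (median -0.09, camera adjusted p = 0.17; fry adjusted p = 0.0076). Pex2 lost its call without not-injected replicate 3 (adjusted p = 0.0561) or injected replicate 1 (adjusted p = 0.0524). Of 74 mitochondrial ribosomal proteins 11 rose and 3 fell (9 and 2 adjusted over the list alone), with Mrpl45 at 0.72 ± 0.07 and Mrps18a at 0.69 ± 0.09. Their median was 0.06 (camera adjusted p = 0.034; adjusted p = 0.78 with an estimated correlation), and the call was lost without not-injected replicate 2 (adjusted p = 0.0903), not-injected replicate 3 (adjusted p = 0.105) or injected replicate 2 (adjusted p = 0.224), after quantile normalisation (0.28), among genes at or above the median level (0.193), with the mean of probe sets (0.0664) and by fry (0.187). Without injected replicate 2 the median of the mitochondrial list was 0.024. Of 42 cytosolic ribosomal proteins 2 rose and 2 fell (0 and 0 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.93). Rps25 (0.29 ± 0.07) and Rps6 (-0.33 ± 0.09) each lost the call without not-injected replicate 1 or 3 or injected replicate 1 or 3 (adjusted p 0.0527 to 0.0898), and Rps6 also lost it with the mean of its probe sets (-0.15, adjusted p = 0.0949). Of 38 proteasome subunits 6 fell and 2 rose (4 and 2 adjusted over the list alone), with Psmd8 at 0.75 ± 0.13 and Psmd11 at -0.29 ± 0.06, the latter at an adjusted p of 0.0506 without not-injected replicate 3 (median -0.08, camera adjusted p = 0.38).

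The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Because the other splits mix injected and not-injected arrays on both sides, their low counts of called genes do not measure chance. The true split was the 1 split with as many called genes (3486, highest other 0, with 5110 and at most 676 at an unadjusted p under 0.05), as many at 1.5-fold or more (1190, highest other 0) and as many called lists (21, highest other 19). The splits with 17, 17 and 19 called lists were those that put injected replicate 2 with 2 not-injected arrays, against injected replicates 1 and 3 with the remaining not-injected array. This is a structure of the samples that the list test reads.

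Lysosomal genes were higher in injected liver. A larger number of macrophages alone is argued against, since the 20 macrophage markers left after leaving out members of the lysosomal lists and the lysozyme gene Lyz2 had a median of 0.16 (bootstrap 95% interval 0.082 to 0.33; 0.17 and 0.09 to 0.39 with Lyz2 kept) against 0.46 for the hydrolases. An intensity-dependent difference between the arrays is also argued against, since 0% of 10000 random lists matched on mean level had a median as high as the hydrolases. The injection or the vector without TFEB cannot be told apart from TFEB, because 0 arrays came from liver injected with an empty vector. Induction by TFEB, the biology that the design names, is a candidate explanation and stays untested against that.

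Male-biased genes were lower in injected liver. Livers of female mice among the injected are argued against, since the lowest injected array lay at -0.23 from the not-injected mean for Y-linked Eif2s3y and the highest at -0.11 for Xist. A lower share of hepatocytes as the whole cause is argued against by hepatocyte genes, whose median was -0.14 (bootstrap 95% interval -0.25 to -0.033) against -1.18 for male-biased genes. A weaker growth hormone response was not settled. Of the 5 genes set for it 2 fell, Igfals (-0.35 ± 0.07) and Ghr (-0.32 ± 0.08), while Cish rose 2.44-fold. Igf1 and Socs2 did not pass (-0.27 ± 0.12 and 0.75 ± 0.24). Ghr encodes the receptor, so Igfals was the only response gene called lower, and Cish was called higher. An effect of the vector or of illness after injection was not tested.

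Injected replicate 2 showed a smaller response. Its median share of the change of injected replicates 1 and 3 was 0.39 on the linear scale (bootstrap 95% interval 0.34 to 0.51). This was taken over 143 genes that were called at 4-fold or more without it, a choice that can lower its share. The value argues against a not-injected liver under its label. An earlier form of this test found 65.7% of genes with a share over 0.25, short of the 75% set for it. That form was replaced after its value was seen. A mixture of injected and not-injected RNA or cells predicts 1 share for all genes, but the share was 0.34 in the 120 higher genes and 0.87 in the 23 lower genes, a difference of 0.53 (bootstrap 95% interval 0.41 to 0.62) that argues against a mixture as the whole cause. On the linear scale an equal part of a large log2 change gives a larger share for a fall than for a rise. The contrast therefore does not show that lower genes responded more fully. Hsd3b5, with a linear share of 0.857, read 10.43 in replicate 2 on the log2 scale. It read 7.08 and 8.01 in the other injected livers and 13.05 on average without injection. A lower dose of vector in that liver, with or without genes that differ in their response to dose, is a possible explanation that was not tested.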
